A study of Mus musculus with 8 samples.

How the data were processed

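RNA was measured in 8 libraries from mouse fetal liver cells (C57BL/6, E14.5), with 2 libraries in each of 4 groups: WT and E2f2 KO progenitors, and WT and E2f2 KO orthochromatic erythroblasts. Per the labels, lineage-depleted cells were cultured overnight with IL-3 at 10 ng/ml and KL conditioned medium. They were then differentiated for 48 h on fibronectin with erythropoietin at 2 U/ml, and orthochromatic erythroblasts were sorted by CD44, Ter119 and forward scatter. Libraries were made from 200 ng of total RNA and read on an Ion Proton instrument.

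The deposited values are RPKM (reads mapped to a gene, scaled to transcript length and to the mapped reads of the library), computed by the authors with 1 value per gene and library. The genome build was mm9 per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. The values were checked: they were not whole numbers and never below 0, and their sums per library lay between 403053 and 516144, so they are neither counts nor TPM. Read depth was not recoverable from the smallest values, because the commonest ratio between low values of 2 libraries covered at most 1.13% of genes. Symbols of 27 genes had been converted to dates, and these were restored from their Entrez IDs. Of the 19534 genes, 19467 had an Entrez ID in the RefSeq reference.

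Values were analysed as log2(RPKM + 1) without further scaling. Genes with at least 1 RPKM in at least 2 libraries were tested, 11622 in all. A linear model with 4 group means over 8 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend (4 residual and 2.86 prior degrees of freedom). The contrasts were KO against WT in each stage, orthochromatic erythroblasts against progenitors in each genotype, and the interaction of these. Tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold over all genes. For gene lists, p values were also adjusted over the list alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

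The 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered globin genes, heme biosynthesis, iron handling, red cell membrane and skeleton, erythroid transcription factors, organelle clearance and autophagy, enucleation and nuclear condensation, cytokinesis machinery, E2F targets of S phase, G2 and mitosis, the E2F and pocket protein family, CDK inhibitors and D cyclins, p53 targets, apoptosis regulators, interferon response, progenitor genes, genes beside E2f2 on its chromosome, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones and oxidative phosphorylation subunits. Markers of 7 other cell types formed the rest: mast cells and basophils, macrophages and monocytes, granulocytes, megakaryocytes, lymphoid cells, hepatoblasts, and endothelial and stromal cells. Lists with at least 4 tested members were tested with limma's camera (preset correlation 0.01, and an estimated correlation beside it) and with fry, with p adjusted over the lists of a contrast. Some genes belong to more than 1 list, and the globin list also holds Ahsp, a chaperone of alpha globin that is not itself a globin gene.

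For each comparison of 2 groups the genes named were the 10 largest rises and 10 largest falls past the threshold that separated the libraries of the groups and reached a mean of 5 RPKM in a group. Where fewer than 5 passed, genes with the smallest p filled the list to 5. For the interaction the 5 largest in each direction were taken in the same way without the condition on separation. E2f2 and Cit were always included, with up to 4 members of each list. Symbols that are only predicted or unassigned were not named. The most abundant markers of myeloid cells, Slc2a1 and Stmn1 were named after their values were seen where they describe a library or a related gene.

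The alternatives were other pseudocounts (0.1 and 5), no filter or a filter at 5 RPKM, median-of-ratios scaling, quantile normalization, no mean-variance trend, the replicate number as a block, leaving out each library, fitting only the 4 libraries compared, an estimated correlation, and fry. Library weights, list tests without any 1 library or with other pseudocounts and filters, and the joint omission of WT progenitor library 1 and WT orthochromatic library 1 were added after the data were seen. The steps were tested on simulated data, 5 simulations with 50 changed genes per size. With libraries as noisy as the KO pairs, the test in orthochromatic erythroblasts found 99.2% of rises and 99.6% of falls of 2 on the log2 scale, and 14.0% of its calls were unchanged genes. With the deviations of WT orthochromatic library 1 it found 0, and after leaving that library out 99.6% and 98.4%, with 24.0% of calls unchanged. In other simulated lists the members shared a random deviation in each library (SD 1 on the log2 scale) but had no difference between groups. Of these, 79 of 100 were called at an unadjusted p under 0.05 with the preset correlation and 5 of 100 with an estimated one. The SD of 1 was chosen and not estimated from the data, so these rates hold for that setting only. For comparison, the replicate medians of the G2 and mitosis list were 5.47 and 5.60 in WT progenitors and 6.38 and 4.53 in WT orthochromatic erythroblasts. In KO they were 5.65 and 5.59, and 3.65 and 3.33.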

Results

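Gene expression was measured in 8 RNA sequencing libraries of mouse fetal liver cells taken at E14.5. Wild type (WT) and E2f2 knockout (KO) cells each gave 2 libraries of lineage-depleted progenitors and 2 libraries of orthochromatic erythroblasts. The erythroblasts were sorted by CD44, Ter119 and cell size after 48 h of differentiation with erythropoietin. E2f2 encodes a transcription factor of the E2F family, which controls genes of DNA replication and cell division. The values are RPKM per gene and library, without read counts, so the depth of each library is not known and a gene listed at 0 was not detectable at that depth. Nothing in the sample descriptions says that the replicates came from separate animals or cultures, so each p measures the spread between these samples. Changes are differences in log2(RPKM + 1) with the standard error (SE) of a limma fit to 4 groups of 2 libraries.

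E2f2 was read in all 8 libraries and was lower in KO. In progenitors it stood at 24.4 and 16.1 RPKM in WT and at 8.51 and 7.70 RPKM in KO. In orthochromatic erythroblasts it stood at 138 and 157 RPKM in WT and at 37.6 and 44.6 RPKM in KO. The values are per gene, so exons outside the deleted part may be read in KO. The difference was −1.20 in progenitors (SE 0.285, adjusted p = 1) and −1.82 in orthochromatic erythroblasts (SE 0.285, adjusted p = 0.337). Leaving out WT orthochromatic library 1 gave −1.91 and adjusted p = 0.0353 in the latter (0.0644 with WT progenitor library 1 left out too), and leaving out WT orthochromatic library 2 gave −1.73 and adjusted p = 0.000802. It was −1.03 after median-of-ratios scaling (adjusted p = 0.348) and −1.25 after quantile normalization (adjusted p = 0.301). E2f2 rose with maturation in both genotypes, by 2.83 in WT (adjusted p = 0.00139) and 2.21 in KO (adjusted p = 0.00134). Citron kinase (Cit), a component of the contractile ring, rose by 1.57 in WT (SE 0.419, adjusted p = 0.0254), which was 0.96 (adjusted p = 0.0961) without WT progenitor library 1. In KO the change of Cit was 0.15 (adjusted p = 0.747), and the test of the difference between the genotypes gave −1.41 (adjusted p = 0.577).

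**Figure D1:**
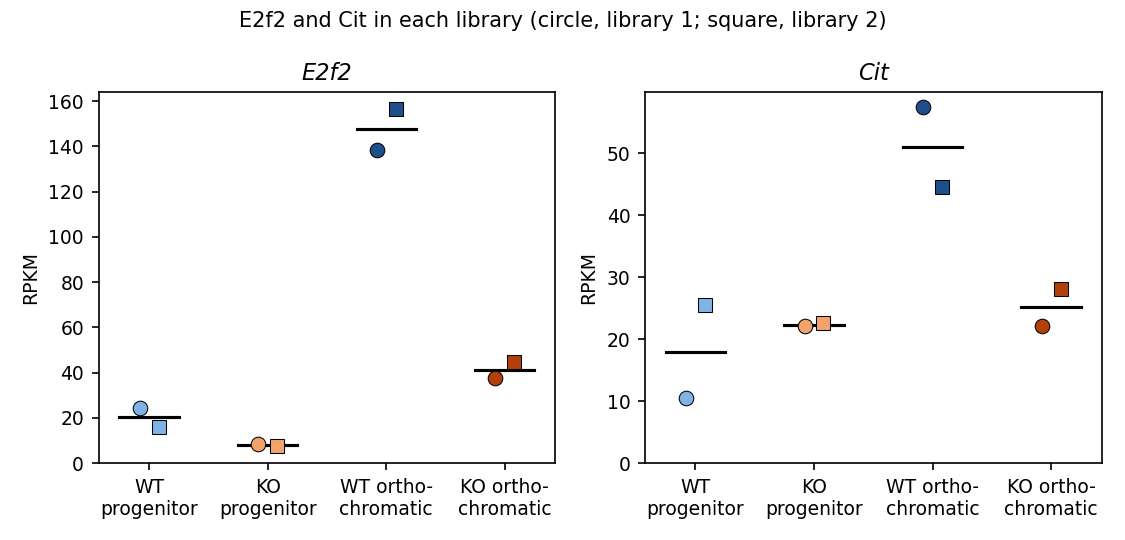
RPKM of E2f2 (left) and Cit (right) in each library, with circles for library 1, squares for library 2 and a bar at the mean of each group of 2. E2f2 lies at 138 and 157 RPKM in WT orthochromatic erythroblasts and at 37.6 and 44.6 RPKM in KO.

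WT orthochromatic library 1 stood apart from the other orthochromatic libraries. Across the 11622 tested genes, which are not independent replicates, it correlated with WT orthochromatic library 2 at r = 0.769, while library 2 correlated with the KO orthochromatic libraries at 0.971 and 0.966. Globin genes made up 16.2% of its RPKM sum, against 43.0% in WT orthochromatic library 2 and 41.4% and 46.9% in KO. Granulocyte markers had a median log2(RPKM + 1) of 6.64 in it, against 0.60 in WT library 2 and 0.00 and 0.17 in KO. Its most abundant myeloid transcripts were S100a9, a neutrophil calcium-binding protein, at 4544 RPKM against 15.0 in library 2, and Lyz2, lysozyme of myeloid cells, at 2868 RPKM against 14.2. Interferon response genes also stood at a median of 7.12 in it and at 0.98, 0.74 and 1.66 in the other orthochromatic libraries. Slc2a1, the glucose transporter of red cells, was at 47.0 RPKM in it and at 1401 RPKM in WT library 2. Leaving out each library of the groups compared in turn was planned for the counts of genes, and its omission from the comparisons it is not part of, the list tests without any 1 library and its joint omission with WT progenitor library 1 were added after the values were seen.

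**Figure D2:**
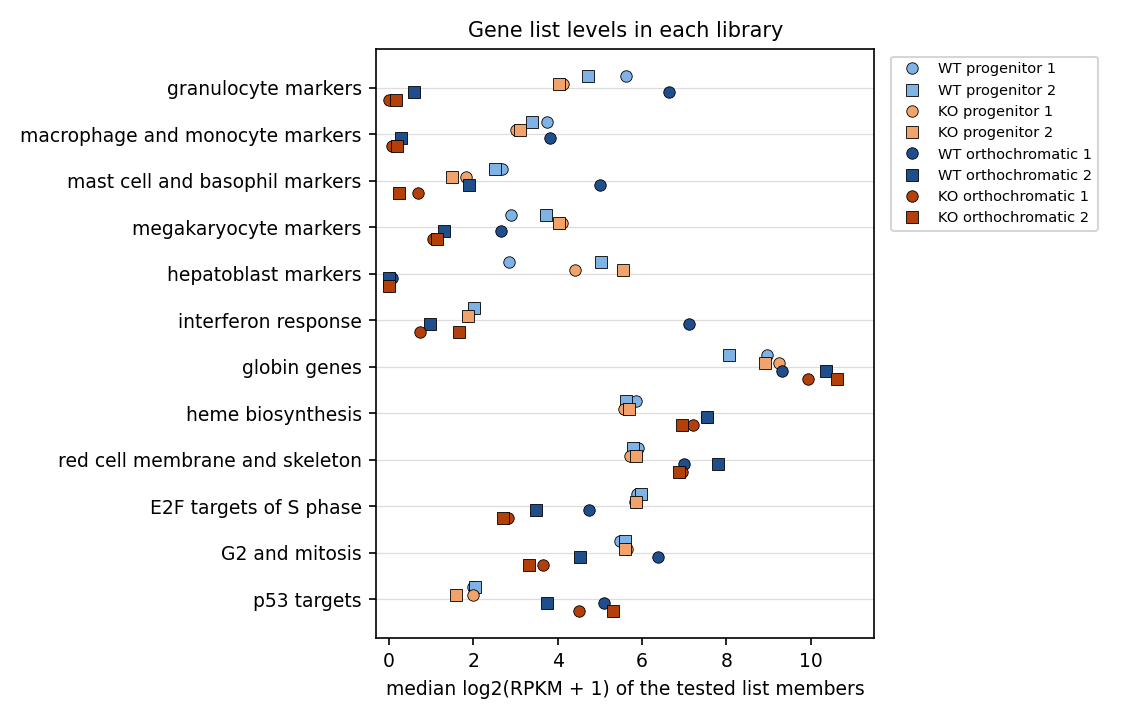
Median log2(RPKM + 1) of 12 gene lists (rows) in each of the 8 libraries, coloured by group, with circles for library 1 and squares for library 2. WT orthochromatic library 1 lies at 6.64 for granulocyte markers and 7.12 for interferon response genes, and the other orthochromatic libraries lie at or below 1.66 for both lists.

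The comparison of KO with WT orthochromatic erythroblasts asks what differs late in erythroid maturation when E2f2 is lost. Genes of G2 and mitosis had lower values in KO: 39 of 40 tested had a negative difference, and 37 of 40 had both KO libraries below both WT libraries (median −1.92, SD 0.545). Of all 11622 tested genes, 4873 had both KO libraries below both WT libraries. Foxm1, a transcription factor of mitotic genes, was at 22.8 and 15.9 RPKM in WT and at 2.41 and 2.52 RPKM in KO. Mki67, a marker of proliferating cells, was at 237.5 and 308 RPKM in WT and at 86.9 and 76.4 RPKM in KO. E2F targets of S phase were also lower, with 41 of 45 differences negative and a median of −1.08. Their median level on the log2 scale was 4.749 in WT library 1 and 3.488 in WT library 2, against 2.827 and 2.711 in KO. Among them Ccne1, the cyclin that drives entry into S phase, was at 32.5 and 16.5 RPKM in WT and at 1.92 and 1.53 RPKM in KO (−3.16, SE 0.348). In contrast, 17 of 23 p53 targets had higher values in KO (median 0.70, SD 0.971). Their median level overlapped between the genotypes, at 5.098 in WT library 1 and 3.735 in WT library 2, against 4.512 and 5.308 in KO. Among the 17 was Eda2r, a receptor of the tumor necrosis factor family, at 0.873 and 1.69 RPKM in WT and at 8.38 and 11.02 RPKM in KO.

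No single gene passed the threshold in this comparison with limma over 11622 genes (0 higher and 0 lower, with 1690 at an unadjusted p under 0.05). Without WT orthochromatic library 1, 17 genes were higher and 84 were lower in KO. With WT progenitor library 1 left out as well, 0 genes passed, so every call named here from the fit without WT orthochromatic library 1 was lost. The differences were the same in both fits, as WT progenitor library 1 enters only the estimate of the spread, and the residual degrees of freedom went from 3 to 2. Without WT orthochromatic library 2, 750 were higher and 6883 were lower, so the count rests on which WT library is used. The median difference of all genes was −0.57, and it was −0.12 without WT library 1, −0.05 after median-of-ratios scaling and 0.06 after quantile normalization. Relative to the median of all genes, the G2 and mitosis list lay at −1.35, the S phase list at −0.50 and the p53 targets at 1.28. In WT orthochromatic library 1 the median of the G2 and mitosis genes was 6.38, against 4.53 in WT library 2 and 3.65 and 3.33 in KO. With WT library 1 left out, the G2 and mitosis genes had 39 of 40 negative differences (median −1.09, SD 0.541).

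In the list tests of this comparison, G2 and mitosis genes were lower in KO (adjusted p = 3.07e-14), which was lost with an estimated correlation (adjusted p = 0.684). Of these 40 genes, 0 passed over all genes and 37 passed when adjusted over the list alone. With WT orthochromatic library 1 left out, 14 were lower over all genes, and 35 were lower and 1 higher adjusted over the list alone (list adjusted p = 1.61e-24, and adjusted p = 0.184 with an estimated correlation). The E2F targets of S phase gave adjusted p = 4.99e-05, and adjusted p = 0.783 with an estimated correlation. Of their 45 genes, 0 passed over all genes and 7 adjusted over the list alone, and without WT library 1 the numbers were 5 and 15. Those 5 included Ccna2, cyclin A2 (−1.48, adjusted p = 0.0232), and Tk1, thymidine kinase (−1.20, adjusted p = 0.0487). The cytokinesis machinery was lower with adjusted p = 0.000923, and adjusted p = 0.783 with an estimated correlation (29 of 32 negative, median −1.63). Its median level was 5.527 in WT library 1 and 4.681 in WT library 2, against 3.66 and 3.551 in KO. Of its members 0 passed over all genes and 13 adjusted over the list alone. Without WT library 1, 11 passed over all genes, among them Aurkb, a kinase of the chromosomal passenger complex (−1.98, adjusted p = 0.0297), and Racgap1, a protein of the central spindle (−1.65, adjusted p = 0.0363).

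The E2F and pocket protein family had 15 of 17 negative differences (median −0.91; adjusted p = 0.0159, and adjusted p = 0.783 with an estimated correlation), and the list gave adjusted p = 0.303 after median-of-ratios scaling, 0.0716 after quantile normalization, 0.348 without WT orthochromatic library 2 and 0.0566 without KO orthochromatic library 2. E2f8, an E2F repressor, was at 40.4 and 31.1 RPKM in WT and at 5.87 and 6.12 RPKM in KO, and E2f7, its closest relative, at 5.20 and 3.63 RPKM in WT and at 0.141 and 0.118 RPKM in KO. The 17 genes include E2f2, the targeted gene, whose fall in KO says nothing about the rest of the family. The list was not tested without it. Of the 17 genes 0 passed over all genes and 3 adjusted over the list alone. In the fit without WT orthochromatic library 1, E2f2, E2f7 and E2f8 passed over all genes, with adjusted p = 0.0353 for E2f7 and adjusted p = 0.0208 for E2f8. The same fit gave lower values in KO for Mxd3, a MAX-binding repressor (−3.10, adjusted p = 0.0208), Asf1b, a histone chaperone (−2.23, adjusted p = 0.0208), and Rps6ka1, a ribosomal S6 kinase (−3.30, adjusted p = 0.0208). It gave higher values for Snx21, a sorting nexin (2.14, adjusted p = 0.0353), Ralgps2 (1.78, adjusted p = 0.0435) and Pmm1, a phosphomannomutase (1.93, adjusted p = 0.0451). Csrnp2 lay at 1.68 with adjusted p = 0.0566.

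The p53 targets were higher in KO in the list test (adjusted p = 1.36e-11), and this was lost with an estimated correlation (adjusted p = 0.477). Of the 23 genes 0 passed over all genes, and adjusted over the list alone 1 was higher and 1 lower. Their median was 1.29 without WT orthochromatic library 1 (adjusted p = 2.50e-15, and adjusted p = 0.301 with an estimated correlation) and 0.15 without WT orthochromatic library 2 (adjusted p = 0.000643). Eda2r passed over all genes without WT library 1 (1.98, adjusted p = 0.0390), and Sesn1, a sestrin, was lower (−1.38, adjusted p = 0.0474). Mdm2, the ubiquitin ligase of p53, stood at 136.5 and 125 RPKM in WT and at 241 and 493 RPKM in KO without passing (1.39, adjusted p = 0.337). Phlda3, an inhibitor of Akt, stood at 15.6 and 5.73 RPKM in WT and at 21.8 and 44.3 RPKM in KO (1.61, adjusted p = 0.337). Cdkn1a, the cell cycle inhibitor p21, stood at 358 and 285 RPKM in WT and at 444 and 703 RPKM in KO (0.81, adjusted p = 0.337).

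**Figure D3:**
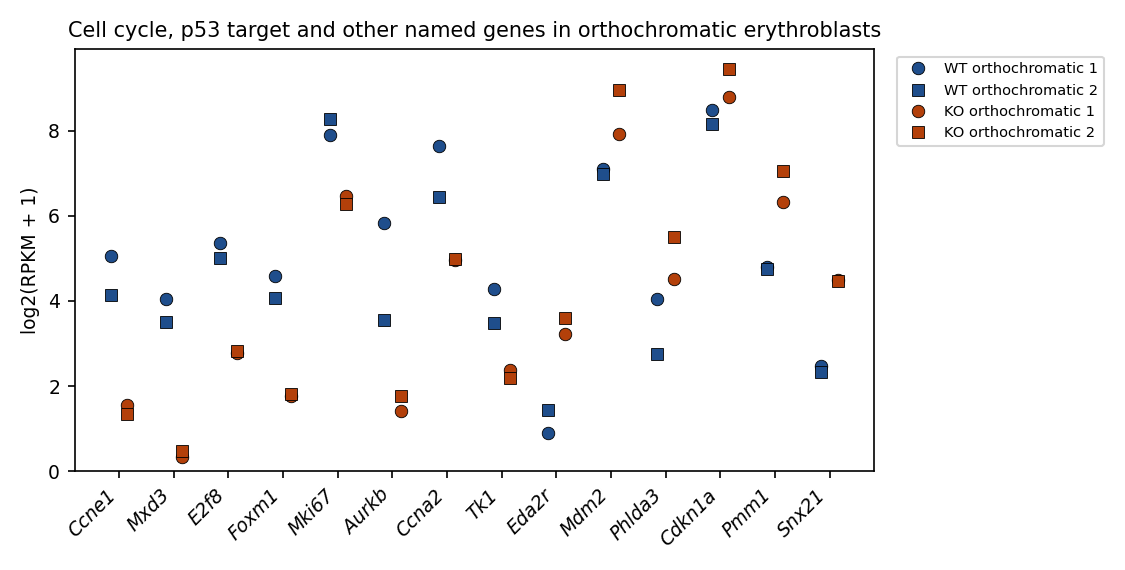
Log2(RPKM + 1) of 14 named genes in the 4 orthochromatic libraries (blue for WT, orange for KO, circles for library 1, squares for library 2). Ccne1 lies at 32.5 and 16.5 RPKM in WT and at 1.92 and 1.53 RPKM in KO, and Eda2r at 0.873 and 1.69 RPKM in WT and at 8.38 and 11.02 RPKM in KO.

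Genes of the red cell itself had smaller median differences between the genotypes, and their direction or call changed without WT orthochromatic library 1. The 9 genes of the globin list, Ahsp among them, were all higher in KO (median 0.55, adjusted p = 5.73e-06, and adjusted p = 0.477 with an estimated correlation). Without that library their median was −0.08, and after quantile normalization of all libraries the test gave adjusted p = 0.115. The near-identical copies among the globin genes make the share of reads given to each copy uncertain. Heme biosynthesis genes had a median of −0.52 (adjusted p = 0.978), and without that library 15 of 16 were lower (median −0.43; adjusted p = 0.000271, and adjusted p = 0.184 with an estimated correlation). After median-of-ratios scaling of all libraries the median of the heme genes was 0.28. The genes of red cell membrane and skeleton had a median of −0.14 (adjusted p = 0.309), which was 0.66 after median-of-ratios scaling and 0.27 after quantile normalization. Without WT library 1, 24 of 26 were lower (median −0.68; adjusted p = 2.67e-09, and adjusted p = 0.184 with an estimated correlation), while without WT library 2 the tests of both the membrane genes (adjusted p = 1.15e-06) and the heme genes (adjusted p = 0.0275) pointed upward. Ermap, an erythroid membrane protein (−1.32, adjusted p = 0.0353), and Tspan33, a tetraspanin (−1.04, adjusted p = 0.0435), were lower over all genes without WT library 1, and 14 of 26 adjusted over the list alone.

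Markers of other blood cells had lower values in KO, and their level was highest in WT orthochromatic library 1. Granulocyte markers had 25 of 25 negative differences (median −3.51; adjusted p = 0.00111, and adjusted p = 0.891 with an estimated correlation), and without that library the median was −0.42 (adjusted p = 0.00703, and adjusted p = 0.606 with an estimated correlation). Mast cell and basophil markers had a median of −2.45 (adjusted p = 0.00843, and adjusted p = 0.783 with an estimated correlation), and without that library −0.47 (adjusted p = 0.00146, and adjusted p = 0.184 with an estimated correlation), while with no filter and all libraries they gave adjusted p = 0.0596. Prss34, a basophil protease, was at 76.3 and 3.37 RPKM in WT and at 0.184 and 0.345 RPKM in KO. Macrophage and monocyte markers had a median of −1.59 (adjusted p = 0.150, and 9.03e-05 after median-of-ratios scaling). Their median level was 3.815 in WT orthochromatic library 1 and 0.292 in WT library 2, against 0.075 and 0.184 in KO, so most of the difference came from WT library 1. Interferon response genes had 27 of 27 negative differences (median −2.81; adjusted p = 0.0155, 0.0661 with a filter at 5 RPKM, 0.0991 without KO orthochromatic library 1, and adjusted p = 0.941 with an estimated correlation), and without that library a median of −0.02 with the test in the other direction (adjusted p = 0.277, and adjusted p = 0.752 with an estimated correlation).

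The comparison of KO with WT progenitors asks what the loss of E2f2 changes before differentiation. The embryonic globin gene Hbb-y stood at 11.8 and 10.4 RPKM in WT and at 101.0 and 73.7 RPKM in KO progenitors (2.86, SE 0.356). Hba-x, the embryonic alpha-like globin gene, stood at 6.08 and 9.33 RPKM in WT and at 68.0 and 35.2 RPKM in KO (2.55, SE 0.463). Stmn1-rs1, a copy of the microtubule regulator stathmin, stood at 0.246 and 0.153 RPKM in WT and at 8.62 and 7.97 RPKM in KO (SE 0.253). Markers of hepatoblasts and megakaryocytes had higher values in KO progenitors, and markers of macrophages and granulocytes had lower values.

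No gene passed the threshold in progenitors with limma over all genes (0 higher and 0 lower, with 117 at an unadjusted p under 0.05). In the simulated data with the deviations of WT orthochromatic library 1, this test found 0% of rises and falls of 2. With libraries as noisy as the KO pairs it found 99.2% of those rises and 100% of those falls. The lack of calls therefore does not show that progenitors were unchanged. The smallest adjusted p was 0.103, for Stmn1-rs1, and Hbb-y had 0.578 and Hba-x 1. WT orthochromatic library 1 enters this comparison only through the shared estimate of the spread. Without it 2 genes passed, Stmn1-rs1 and Hbb-y (adjusted p = 0.00638 each), and Hba-x had 0.146. With WT progenitor library 1 left out as well, 0 genes passed, with Stmn1-rs1 at 3.01 (adjusted p = 0.154) and Hbb-y at 2.94 (adjusted p = 0.256). Reads of Stmn1-rs1 are hard to tell from those of Stmn1, which stood at 694 and 604 RPKM in WT and at 514 and 487 RPKM in KO progenitors. Arl5a, a GTPase of the Golgi apparatus, was at 37.6 and 40.3 RPKM in WT and at 9.95 and 12.9 RPKM in KO (−1.70, adjusted p = 1).

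Hepatoblast markers had 25 of 25 positive differences in progenitors (median 0.98; adjusted p = 2.36e-17, and adjusted p = 0.528 with an estimated correlation), with 0 of 25 passing over all genes or adjusted over the list alone. Their median level was 2.84 in WT progenitor library 1, 5.02 in WT library 2, and 4.40 and 5.54 in KO. Without WT progenitor library 1 the median difference was 0.15 (adjusted p = 0.00442), and without WT progenitor library 2 it was 1.83. Rbp4, the retinol carrier made in liver cells, stood at 9.97 and 49.5 RPKM in WT and at 51.8 and 100.7 RPKM in KO. Megakaryocyte markers had 19 of 20 positive differences, and 17 of 20 had both KO libraries above both WT libraries, as did 2487 of all 11622 tested genes. The median of these markers was 0.93 (adjusted p = 7.08e-13, and adjusted p = 0.528 with an estimated correlation). None of the 20 passed over all genes or adjusted over the list alone. Their median was 0.63 without WT progenitor library 1 (adjusted p = 1.76e-10) and 1.22 without WT progenitor library 2. Itga2b, the platelet integrin, stood at 14.48 and 33.9 RPKM in WT and at 53.2 and 47.8 RPKM in KO. Endothelial and stromal markers had a median of 0.69 (adjusted p = 1.51e-11, and adjusted p = 0.528 with an estimated correlation), and 0.28 without WT progenitor library 1. The globin list, which includes Ahsp, had a median of 0.58 (adjusted p = 3.97e-06, and adjusted p = 0.528 with an estimated correlation), with 2 of 9 genes passing adjusted over the list alone. Without WT progenitor library 2 the globin median was 0.16 (adjusted p = 0.533).

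Macrophage and monocyte markers had 26 of 28 negative differences in progenitors (median −0.47; adjusted p = 4.98e-07, and adjusted p = 0.855 with an estimated correlation). Granulocyte markers had 23 of 25 (median −0.70; adjusted p = 4.13e-05, and adjusted p = 0.938 with an estimated correlation), and without WT progenitor library 1 their median was −0.44 (adjusted p = 0.181). Ms4a3, a membrane protein of granulocyte precursors, stood at 122 and 62.2 RPKM in WT and at 34.9 and 31.7 RPKM in KO. None of these genes passed over all genes or adjusted over the list alone. The cell cycle lists that were lower in KO orthochromatic erythroblasts lay near 0 in progenitors, with medians of 0.02 for G2 and mitosis (adjusted p = 0.420) and −0.04 for E2F targets of S phase (adjusted p = 0.0503, and 0.00663 after median-of-ratios scaling). The p53 targets lay at 0.04 (adjusted p = 0.848). The genes beside E2f2 on its chromosome had a median of −0.16 (adjusted p = 0.0151, and adjusted p = 0.938 with an estimated correlation), and −0.07 without WT progenitor library 1 (adjusted p = 0.476).

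The comparison of orthochromatic erythroblasts with progenitors asks what changes with maturation, in WT and in KO. It sets sorted erythroblasts against lineage-depleted cells that also held RNA of other cell types. Hepatoblast markers had median log2 values of 2.84 and 5.02 in WT and 4.40 and 5.54 in KO progenitors, and at most 0.071 in orthochromatic libraries. Rises and falls with maturation therefore mix changes within erythroid cells with differences in the cells present. The list tests were up for heme biosynthesis, globin genes, red cell membrane and organelle clearance in both genotypes and down for hepatoblast markers and E2F targets of S phase, although some members of the former lists fell. With an estimated correlation, of these lists only heme biosynthesis (adjusted p = 0.0365 in WT and 0.0313 in KO) and organelle clearance (adjusted p = 0.0247 and 0.0187) passed, and the calls were lost for globin genes (adjusted p = 0.468 and 0.305), red cell membrane (adjusted p = 0.183 and 0.131) and both hepatoblast markers and E2F targets of S phase (adjusted p = 0.648 and 0.752). Alas2, the first enzyme of erythroid heme synthesis, rose by 5.74 in WT (SE 0.674, adjusted p = 0.00184) and 6.32 in KO (SE 0.674, adjusted p = 0.000778), and Slc4a1, the band 3 anion exchanger, by 4.35 in WT (adjusted p = 0.00204) and 4.48 in KO (adjusted p = 0.00107). The cell cycle inhibitor Cdkn1a rose from 2.78 and 2.96 RPKM to 358 and 285 RPKM in WT, and from 2.98 and 1.44 RPKM to 444 and 703 RPKM in KO. Alb, serum albumin, fell from 70.4 and 365.5 RPKM to 0.163 and 0 RPKM in WT, and from 264 and 639 RPKM to 0.190 and 0.0619 RPKM in KO.

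In WT 666 genes rose and 3857 fell with maturation, and in KO 752 rose and 7102 fell. With only the 4 libraries compared, 0 genes passed in WT, while in KO 1133 rose and 9203 fell. With library weights 209 rose and 986 fell in WT, and 1172 rose and 9250 fell in KO. Globin genes filled 41.4% to 46.9% of the RPKM sum in 3 of the 4 orthochromatic libraries and 0.826% to 1.75% in progenitors, and the median of all genes moved by −0.90 in WT and −1.61 in KO. That shift was −0.18 and −0.40 after median-of-ratios scaling, which gave 1348 up and 2045 down in WT and 2136 up and 3163 down in KO. After quantile normalization the shift was −0.05 and −0.08, with 1582 up and 2066 down in WT and 2351 up and 2538 down in KO. Without WT orthochromatic library 1, 1104 rose and 7990 fell in WT. The sum of both directions in WT was 2604 without WT progenitor library 1 and 1834 without WT progenitor library 2. In KO it lay between 4458 and 4750 when either KO progenitor library or either KO orthochromatic library was left out.

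The heme biosynthesis list was up in both genotypes, with 10 of 16 genes up and 1 down in WT and 9 up and 3 down in KO. The same numbers passed adjusted over the list alone. Its median lay 2.21 above that of all genes in WT and 2.77 above it in KO. The list passed in WT (adjusted p = 5.38e-09, and adjusted p = 0.0365 with an estimated correlation) and in KO (adjusted p = 1.32e-09, and adjusted p = 0.0313 with an estimated correlation). Organelle clearance and autophagy had 15 of 26 genes up and 2 down in WT and 13 up and 3 down in KO, and adjusted over the list alone 16 up and 2 down in WT. It passed in WT (adjusted p = 5.69e-14, and adjusted p = 0.0247 with an estimated correlation) and in KO (adjusted p = 4.42e-16, and adjusted p = 0.0187 with an estimated correlation). Map1lc3b, a protein of autophagosomes, rose by 2.56 in WT and 2.76 in KO, and Ube2l6, a conjugating enzyme for the ubiquitin-like Isg15, by 4.30 in WT and 3.75 in KO. Leaving out WT orthochromatic library 1 moved the estimated-correlation p of both lists to 0.0546 in WT and 0.0622 in KO.

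Red cell membrane and skeleton genes had 17 of 26 up and 0 down in WT, and 16 up and 3 down in KO, or 19 and 17 up adjusted over the list alone. Their tests gave adjusted p = 2.55e-16 in WT (adjusted p = 0.183 with an estimated correlation) and 7.87e-18 in KO (adjusted p = 0.131 with an estimated correlation). Gypa, glycophorin A, rose by 3.35 in WT and 3.30 in KO. The globin list, which includes Ahsp, had 5 of 9 genes up and 2 down in WT and 6 up and 2 down in KO. The 2 that fell were the embryonic genes Hbb-y and Hba-x. In KO Hbb-y fell by 4.58 (adjusted p = 0.000465) and Hba-x fell by 3.66 (adjusted p = 0.00125). The test of the globin list gave adjusted p = 1.01e-05 in WT (adjusted p = 0.468 with an estimated correlation) and 1.81e-07 in KO (adjusted p = 0.305 with an estimated correlation). The p53 targets had 12 of 23 up and 0 down in WT and 14 up and 0 down in KO. Their test gave adjusted p = 1.26e-14 in WT (adjusted p = 0.210 with an estimated correlation) and 1.31e-21 in KO (adjusted p = 0.131 with an estimated correlation). Trp53inp1, a stress protein induced by p53, rose by 5.79 in WT and 6.32 in KO.

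E2F targets of S phase had 33 of 45 genes down in WT and 43 down in KO, or 39 and 43 adjusted over the list alone, where 1 also rose in KO. Their tests gave adjusted p = 1.01e-05 in WT (adjusted p = 0.648 with an estimated correlation) and 3.79e-05 in KO (adjusted p = 0.752 with an estimated correlation). Dnmt1, the maintenance DNA methyltransferase, fell by 2.13 in WT and fell by 3.21 in KO, and the test of the difference between these gave −1.07 (adjusted p = 0.577). In the G2 and mitosis list 2 of 40 genes rose and 1 fell in WT, while 1 rose and 35 fell in KO. Cdc25b, a phosphatase that activates mitotic kinases, rose in WT (3.04, adjusted p = 0.00138) and in KO (3.21, adjusted p = 0.000666). The WT list test was up with adjusted p = 0.00954 (adjusted p = 0.804 with an estimated correlation) although its median was −0.23, where the median of all genes was −0.90. With no filter the WT test gave adjusted p = 0.204. After median-of-ratios scaling the WT median of this list was 0.76, and after quantile normalization 0.37. The KO list test was down with adjusted p = 0.182, and 0.00601 after quantile normalization. With WT orthochromatic library 1 left out, 29 of the 40 fell and 2 rose in WT, and the WT list test gave adjusted p = 0.989 (median −1.03), while without WT library 2 it gave adjusted p = 6.27e-06 (median 0.57).

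Hepatoblast markers fell in 23 of 25 genes in WT and 25 of 25 in KO (adjusted p = 1.01e-05 in WT and 0.000121 in KO, and adjusted p = 0.648 and 0.752 with an estimated correlation). Subunits of oxidative phosphorylation fell in 63 of 90 genes in WT and 74 of 90 in KO (adjusted p = 1.01e-05 and 0.000482, and adjusted p = 0.648 and 0.752 with an estimated correlation). The former list gave adjusted p = 0.108 in WT without WT orthochromatic library 1, and the latter 0.875 in KO after median-of-ratios scaling. Atp5a1, a subunit of the ATP synthase, fell from 604 and 615 RPKM to 157 and 122 RPKM in WT. Cytosolic ribosomal proteins fell in 32 of 78 genes in WT and 55 of 78 in KO, with a list test of adjusted p = 0.0175 in WT (adjusted p = 0.804 with an estimated correlation) and 0.0923 in KO. The WT call was also lost after median-of-ratios scaling (median −1.19 to −0.19, adjusted p = 0.683), with a filter at 5 RPKM (adjusted p = 0.0676), without WT progenitor library 1 (adjusted p = 0.112) and without WT orthochromatic library 2 (adjusted p = 0.0653). Their median change in KO was −1.60, and it was 0.28 after median-of-ratios scaling, while after quantile normalization the KO test was down (adjusted p = 2.73e-06). Interferon response genes rose in 5 of 27 in WT and 3 of 27 in KO. Among these Oasl2, an interferon-induced protein, rose by 7.28 in WT and 6.40 in KO, and Isg15, a ubiquitin-like modifier, by 6.03 in WT (adjusted p = 0.0254). Isg15 no longer passed without WT progenitor library 1 (6.25, adjusted p = 0.0992) or library 2 (5.82, adjusted p = 0.132), with a change of about the same size. Their median in WT was 1.75, and it was −0.81 without WT orthochromatic library 1, where the test was still upward against other genes (adjusted p = 0.0275, and adjusted p = 0.675 with an estimated correlation), and 5.06 without WT library 2. The tests of this list gave adjusted p = 1.55e-09 in WT (adjusted p = 0.648 with an estimated correlation) and 1.17e-05 in KO (adjusted p = 0.752 with an estimated correlation), the latter upward although the median was −0.85, which was −0.01 after median-of-ratios scaling and 0.72 after quantile normalization. WT orthochromatic library 1 held Isg15 at 992 RPKM and WT library 2 at 21.8 RPKM.

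**Figure D4:**
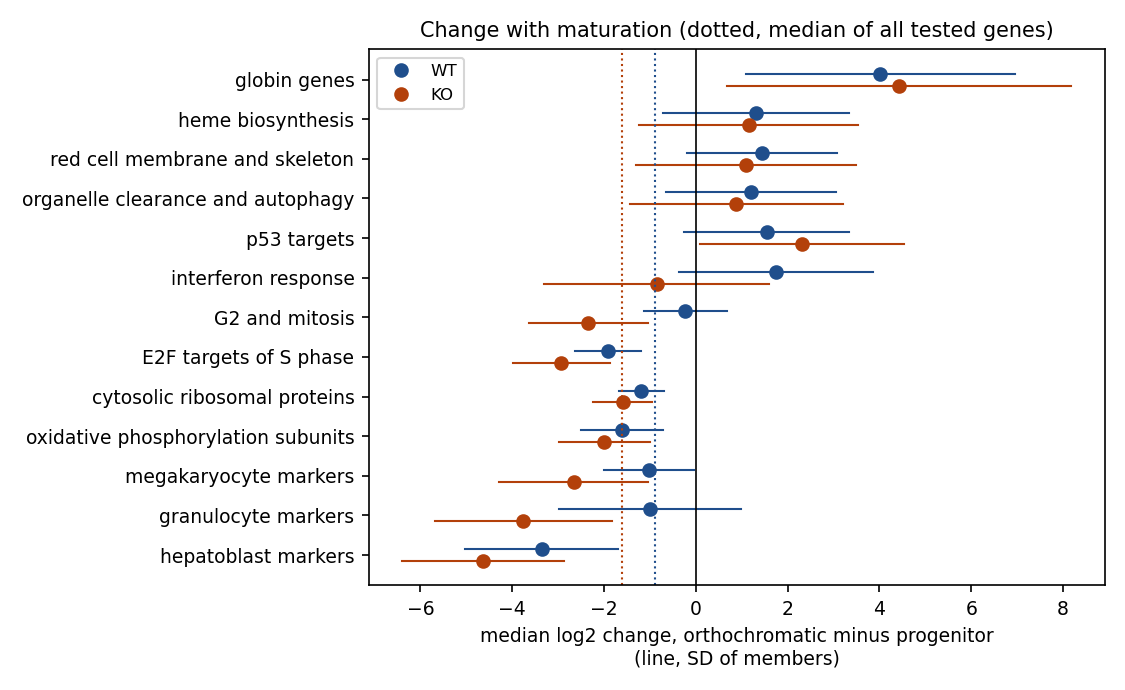
Median log2 change from progenitors to orthochromatic erythroblasts of 13 gene lists in WT (blue) and KO (orange), with lines for the SD of the members and dotted lines at the medians of all genes (−0.90 and −1.61). Globin genes lie at 4.02 in WT and 4.43 in KO and hepatoblast markers at −3.36 and −4.63, while after median-of-ratios scaling ribosomal proteins move from −1.60 to 0.28 in KO and G2 and mitosis genes from −0.23 to 0.76 in WT, and after quantile normalization interferon response genes from −0.85 to 0.72 in KO.

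The interaction asks whether maturation differed between the genotypes. Ccne1 went from 99.1 and 113 RPKM to 32.5 and 16.5 RPKM in WT, and from 89.8 and 94.2 RPKM to 1.92 and 1.53 RPKM in KO (difference of changes −2.96, SE 0.493). Mxd3 went from 3.47 and 3.83 RPKM to 15.45 and 10.3 RPKM in WT and from 2.53 and 4.02 RPKM to 0.259 and 0.394 RPKM in KO (−3.22, SE 0.542). Moap1, a modulator of apoptosis, was at 7.79 and 7.05 RPKM in WT progenitors and at 0.322 and 0 RPKM in WT orthochromatic erythroblasts. In KO it was listed at 0 and at 1.845 RPKM in progenitors and at 4.36 and 2.02 RPKM in orthochromatic erythroblasts (4.12, SE 0.791). G2 and mitosis genes had 39 of 40 negative differences of changes (median −2.02, SD 0.590), and the p53 targets had 15 of 23 positive ones (median 0.66, SD 1.009).

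No gene passed for the interaction with limma (0 up and 0 down, with 588 at an unadjusted p under 0.05), and the genes named here had adjusted p = 0.577. Without WT orthochromatic library 2 the count was 541 up and 6212 down, and without WT library 1 it was 0. The list of G2 and mitosis genes passed (adjusted p = 3.99e-13), and this was lost with an estimated correlation (adjusted p = 0.890). Without WT library 1 its median was −1.09 (adjusted p = 7.23e-20, and adjusted p = 0.314 with an estimated correlation), and adjusted over the list alone 33 were lower and 1 higher. The p53 targets passed with adjusted p = 5.98e-11, and this was lost with an estimated correlation (adjusted p = 0.457). Their median was 1.17 without WT library 1 (adjusted p = 1.11e-12, and adjusted p = 0.381 with an estimated correlation) and −0.12 without WT library 2, where the test was still upward against other genes (adjusted p = 0.000483). Of the interaction list calls none held with an estimated correlation.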

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

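The list tests of the interaction, the estimated correlation and both scalings were planned. The tests of explanations were chosen after the result was seen, except the test of strain alleles around E2f2 and the test of Stmn1 reads shared in the same way in both genotypes, and so were the list tests without WT orthochromatic library 1 or another library and with other pseudocounts.

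The list test of the interaction itself passed for 8 gene lists, but 0 genes passed, and none of the 8 lists held with an estimated correlation. The G2 and mitosis genes gave adjusted p = 3.99e-13 (median −2.02, and adjusted p = 0.890 with an estimated correlation) and p53 targets 5.98e-11 (median 0.66, and adjusted p = 0.457 with an estimated correlation). The E2F targets of S phase gave adjusted p = 0.00294 (median −1.07), the cytokinesis machinery 0.00545 (median −1.56) and megakaryocyte markers 0.0112 (median −1.54), each with adjusted p = 0.941 with an estimated correlation. Replication-dependent histones gave adjusted p = 0.000247 although their median was 0.01 (adjusted p = 0.284 with an estimated correlation), and their near-identical copies make single genes uncertain. Progenitor genes gave adjusted p = 0.00545, upward although their median was −0.46 (adjusted p = 0.941 with an estimated correlation). Organelle clearance and autophagy gave adjusted p = 0.0476, upward although its median was −0.51 (adjusted p = 0.457 with an estimated correlation). The median of all genes was −0.68 in this comparison. Without WT orthochromatic library 1 the histones gave adjusted p = 0.561 and organelle clearance 0.489, and the other lists stayed under 0.05, with adjusted p = 0.0126 for progenitor genes and 0.0112 for megakaryocyte markers. Over both scalings and each library left out, only the G2 and mitosis genes and the p53 targets stayed under 0.05 throughout. The E2F targets of S phase gave adjusted p = 0.132 after median-of-ratios scaling (median −0.23), and without WT progenitor library 2 they gave adjusted p = 0.0760 and the cytokinesis machinery 0.0608. Megakaryocyte markers gave adjusted p = 0.0731 without WT progenitor library 1 and 0.0989 with a pseudocount of 0.1, and progenitor genes gave 0.506 after median-of-ratios scaling, 0.510 after quantile normalization and 0.268 without WT orthochromatic library 2.

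WT orthochromatic library 1 stood apart from the other orthochromatic libraries. Its granulocyte markers lay 6.04 above the highest of the others on the log2 scale, with S100a9 at 4544 RPKM and Lyz2 at 2868 RPKM. RNA of myeloid cells in the library is therefore a candidate source. The cells had been sorted by CD44, Ter119 and forward scatter, but how pure that sort was is not known here. Carry-over of progenitor cells as sampled, with their hepatoblasts, was argued against, since the median hepatoblast marker stood at 0.0983% of its level in WT progenitors (Alb at 0.163 RPKM against 218, with Apoe as an exception at 105.5%), but carry-over of blood progenitors without hepatoblasts is left open, since the median log2 value of progenitor genes was 3.54 in this library, 2.90 and 3.33 in WT progenitors, and 0.44 to 0.64 in the other orthochromatic libraries. Interferon response genes had a median log2 value of 7.12 in this library and of 2.02 and 2.01 in WT progenitors. Carry-over of cells at those sampled levels would not account for that list. Dilution of otherwise like erythroblasts would lower red cell genes by a common amount, and other cells could only add to it. The adult globin genes lay at a median log2 ratio of −1.23 to WT orthochromatic library 2. Of 42 heme and membrane genes, 6 (14.3%) lay further below by over 2 SD, at −4.86 (Slc2a1) to −1.82 (Epb4.2). These values argue against dilution alone for those 6 genes. For the other genes, which did not lie further below by that margin, dilution remains open. No biological explanation was tested, as the labels give no group for this library alone.

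G2 and mitosis genes were lower in KO orthochromatic erythroblasts. WT orthochromatic library 1 alone was argued against, since without it the median was −1.09 (SD 0.541). Scaling of the deposited values was argued against too: without that library the median lay at −0.975 relative to all genes, and at −1.17 after median-of-ratios scaling and −1.23 after quantile normalization of all libraries. The SD of the members over the square root of their number was 0.0855 for the first of these. That value treats the genes as independent and does not measure the spread between libraries. KO erythroblasts further along the course of maturation cannot be told apart from a direct effect of E2f2: red cell genes that rise in both genotypes had a median difference of 0.44 from WT library 1 and −0.67 from WT library 2, which point in opposite directions. Of these 21 genes, 5 were lower in KO than in WT library 1 and 20 were lower than in WT library 2. WT library 1 is the one that stood apart. Against WT library 2 the values of these 21 genes run counter to KO cells being further along, but they rest on that 1 WT library. Other lists that changed with maturation pointed both ways against it. Organelle clearance, which rose, had a median of 5.655 in WT library 2 against 5.563 and 5.246 in KO. But the p53 targets, which also rose, were at 3.735 against 4.512 and 5.308. The S phase list, which fell, was at 3.488 against 2.827 and 2.711. These values therefore do not settle the stage. The loss of E2f2 itself stays open, as the design confounds it with any shift in stage between the sorted cells.

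Stmn1-rs1 was near 8 RPKM in KO progenitors and near 0 in WT progenitors. Reads of Stmn1 shared with this copy in the same way in both genotypes were argued against, since the ratio of the copy to Stmn1 differed 54.0 times between KO and WT progenitors. A fixed share of Stmn1 reads assigned to the copy in KO libraries is a candidate explanation: the copy stood at 1.68% and 1.64% of Stmn1 in KO progenitors and at 1.36% and 1.96% in KO orthochromatic erythroblasts, a ratio of group means that differed 1.01 times, while Stmn1 itself differed 22.9 times. Stmn1 lies on the chromosome of E2f2, with 27 tested genes between, so alleles of another strain around the targeted locus may be read as the copy. The 40 genes nearest E2f2, which include neither Stmn1 nor its copy, lay at percentile 89.7 of windows of 40 genes for their absolute difference in progenitors. That test does not examine how reads of Stmn1 were assigned, so strain alleles stay open.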

How the results depend on the processing

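Library weights, the omission of any library from the list tests, the other pseudocounts and filters in them, the omission of WT orthochromatic library 1 from the comparisons it is not part of, and the joint omission of the latter with WT progenitor library 1 were added after the data were seen, and the other alternatives were planned. Where a library left out reduces its group to 1, the lone sample is assumed to vary like the other groups. The number of genes past the threshold was within 1.5 times the reported one in all 5 comparisons with a pseudocount of 0.1, either other filter, no trend, median-of-ratios scaling and the replicate block. In orthochromatic erythroblasts (0 genes with limma) it was 0 to 7633 over libraries left out, with 101 without WT library 1, 0 when WT progenitor library 1 was left out too, and 7633 without WT library 2. In progenitors (0 genes) it was 1 with a pseudocount of 5, 2 with library weights, 1 with only the 4 libraries compared, 0 to 2 over libraries left out, and 0 with WT progenitor library 1 and WT orthochromatic library 1 left out together. For maturation in WT (4523) it was 1195 with library weights, 0 with only the 4 libraries compared, 1834 to 9094 over libraries left out, and 9489 with that pair left out. For maturation in KO (7854) it was 4889 after quantile normalization and 4458 to 10069 over libraries left out. For the interaction (0) it was 0 to 6753 over libraries left out, with 6753 without WT orthochromatic library 2. The E2f2 difference in orthochromatic erythroblasts was −1.94 to −1.70 over libraries left out, −1.03 after median-of-ratios scaling and −1.25 after quantile normalization (−1.82 reported). With the replicate block the counts were 0, 0, 4055, 7607 and 0, but replicate deviations correlated between groups at r of only −0.02 to 0.13 across genes, so the numbers do not pair the libraries. Of the 59 list tests named in the text, directions reversed in these, counting those past the threshold in at least 1 of the 2 settings: in orthochromatic erythroblasts without WT library 1, red cell membrane and skeleton (adjusted p = 2.67e-09, 4.84e-09 with WT progenitor library 1 left out too, and up to 0.499 over libraries left out) and interferon response (0.277, 0.280 with that pair left out, from 1.30e-07 over libraries left out, and 0.752 with an estimated correlation); heme biosynthesis without WT library 2 (upward at 0.0275, against downward at 0.000271 without WT library 1 and up to 0.912); with fry, iron handling (adjusted p = 0.00112), G2 and mitosis (0.871) and histones (0.322) for maturation in WT, and organelle clearance (0.247), progenitor genes (0.694) and histones (0.558) for the interaction; organelle clearance for the interaction with that pair left out (0.966); and ribosomal proteins for maturation in KO after median-of-ratios scaling (0.0405). Of the other list tests, among 130 in all, 29 reversed in at least 1 alternative, 10 of them without WT orthochromatic library 1, with 6 of these for the interaction. Fry does not compare a list with other genes, and camera does, while for the other reversals and the counts the cause was not tested. Of 59 list tests 42 lost their call with an estimated correlation and 17 were the same. For named genes 24 lost their call with only the 4 libraries compared. The 4-library fit was not made for the interaction, which needs all 8, and was not applied to the list tests, which take neither library weights nor the choice of trend from the fit, so that their values under those settings repeat the reported ones. Depth is not known, so no limit could be set for genes listed at 0.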

Other observations

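Regulators of the cell cycle moved both ways with maturation. Cdkn1b, the inhibitor p27, rose by 3.52 in WT (SE 0.249, adjusted p = 0.00101) and 3.06 in KO (adjusted p = 0.000500), and Cdk4, a kinase of the G1 phase, fell by 4.21 in WT (adjusted p = 0.00144) and fell by 5.03 in KO (adjusted p = 0.000571). In the list of CDK inhibitors and D cyclins 3 of 11 genes rose and 3 fell in WT (adjusted p = 0.0345, and adjusted p = 0.560 with an estimated correlation). This call was also lost after median-of-ratios scaling (adjusted p = 0.202), after quantile normalization (0.266), with no filter (0.110), without WT progenitor library 2 (0.0659) and without WT orthochromatic library 2 (0.265). Among apoptosis regulators Pim1, a survival kinase, rose by 3.97 in WT (adjusted p = 0.00104), and Bcl2l1, the survival protein Bcl-xL, stood at 38.9 and 364 RPKM in WT orthochromatic erythroblasts and at 260.5 and 334 RPKM in KO. That list had 3 of 23 genes up and 2 down in WT (adjusted p = 0.0887). Among progenitor genes Myc fell by 3.20 in WT (adjusted p = 0.00112), and 3 of 29 rose and 12 fell (adjusted p = 0.755).

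Ranbp10, a tubulin-binding protein of blood cells in the enucleation list, rose by 3.87 in WT (adjusted p = 0.00104) and 3.62 in KO. In that list 6 of 33 genes rose and 8 fell in WT (adjusted p = 0.0887). Steap3, the iron reductase of the transferrin cycle, fell by 3.46 in WT (adjusted p = 0.00137), and in the iron handling list 5 of 17 genes rose and 7 fell (adjusted p = 0.659). Bcl11a, a repressor of globin genes, fell by 3.46 in WT (adjusted p = 0.00101), while Sox6 rose by 2.53 in WT and 1.71 in KO. Erythroid transcription factors had 7 of 22 genes up and 8 down in WT (adjusted p = 0.0505), with a median of −0.20 that was 0.79 after median-of-ratios scaling. That median was −0.16 without WT orthochromatic library 1 and −0.50 without WT orthochromatic library 2. Replication-dependent histones had 3 of 47 up and 4 down in WT (adjusted p = 0.00364, and adjusted p = 0.183 with an estimated correlation). Without WT orthochromatic library 2 the histones gave adjusted p = 0.359, and they gave 0.0799 after median-of-ratios scaling, 0.0565 with no filter and 0.104 with a filter at 5 RPKM. Of the lymphoid markers 3 were tested and 0 passed in WT, and of the mitochondrially encoded genes 0 were in the table.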
